A study of Homo sapiens with 6 samples.

How the data were processed

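Gene expression was measured on Affymetrix 3' expression arrays with 54675 probe sets, using biotin-labelled target made with the GeneChip 3' IVT Express kit from total RNA (Qiagen RNeasy), per the labels. The 6 samples were untreated H4 cells, H4 cells kept with 1 mM hydrocortisone for 12 h, 24 h, 48 h or 5 d, and T84 cells, each as 1 array, with cells grown on dishes to near confluence. The dose is printed as the labels give it; it is high for a glucocorticoid, and nothing in the sources used here allows its unit to be checked. The labels name no replicate, batch, passage or array date, and no untreated H4 sample has a time point of its own.

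The deposited values are on the log2 scale, 1 per probe set and array, and ran from 2.49 to 14.4. The submitters' processing notes name GCRMA, a background correction with quantile normalisation. Its version and settings are not given in the sources used here, so how far it stretches or compresses the folds of dim genes is unknown. GCRMA values often pile up close to a lowest value, but here at most 0.505% of the probe sets of an array lay within 0.25 of its lowest value. Whether GCRMA made the deposited values is therefore uncertain, which bears on the floor and on every fold of a dim gene. No array image or probe-level file was used here, and the values were taken as deposited with no further normalisation.

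Probe sets were given gene symbols from the platform annotation. Of the 54675 probe sets, 41097 had 1 symbol, 1801 had several and 11777 had none, and 41043 of those with 1 symbol were matched by Entrez identifier to the RefSeq gene table of GRCh38.p14, which was used for names and chromosomes only. Each gene was represented by the probe set with 1 symbol that had the highest mean over the 6 arrays, which gave 19731 genes. Probe sets with several symbols or none were set apart. Genes of the Y chromosome and the X-inactivation transcripts were left out of the results.

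Values under a floor of 4 were raised to 4 before any difference was taken, and 17496 genes were at or above this floor in at least 1 array. A gene counted as higher or lower when the floored difference was 2-fold or more. A fold with 1 array under the floor is printed as "at least", and no fold is given with both arrays under it. The comparisons were each hydrocortisone array against untreated H4, all 4 times together (the same direction and 2-fold or more at each), T84 against untreated H4, and the closeness of each H4 array to T84.

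Since each group held 1 array, no test within a time could be made, and the number of arrays limits the precision. The main test across genes pooled the 4 hydrocortisone arrays (n = 4) against the lone untreated array (n = 1) with limma, two-sided, using empirical Bayes moderation with trend and robust options over 16530 genes with a mean of at least 4 and a Benjamini-Hochberg adjusted p under 0.05. The lone array is assumed to vary like the others, and differences between times count as noise in this fit. A fit of the same kind for T84 (n = 1) against the 5 H4 arrays (n = 5), over 16691 genes, was added after the data were seen, and it takes the 5 H4 arrays as replicates although they differ in treatment. For the fixed lists the adjusted p was also computed over the list alone.

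A total of 21 gene lists with 448 measured members of 486 were fixed, together with the comparisons, the threshold, the floor and the rule for named genes, before the data were examined. A list's median difference was placed among the medians of 10000 random lists of the same size matched on 20 bins of mean expression. Percentiles outside 2.5 to 97.5 are called outside the random range. They rank genes within 1 pair of arrays, so they are not replicate tests, and members of a list are not independent. The lists covered glucocorticoid receptor targets, steroid handling, metallothioneins, brush border and absorptive enterocyte genes, epithelial identity, secretory lineages, crypt and Wnt genes, mesenchymal and smooth muscle markers, TGF-beta and YAP responsive genes, inflammatory genes, Toll-like receptor and NF-kappaB signalling, interferon response, cell cycle, lipid storage, cholesterol synthesis, hypoxia and glycolysis, unfolded protein response, haematopoietic and endothelial markers, neural markers and housekeeping genes.

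All hydrocortisone differences share the untreated array, so an error in that array enters each of them. Its effect was simulated with 200 sets of no-effect arrays that draw their noise from the 24 h minus 12 h and the 5 d minus 48 h differences. Those pairs were the closest H4 arrays, at root mean square log2 differences of 0.203 and 0.206. The untreated array lay 0.263 to 0.471 from the hydrocortisone arrays. If it came from another culture or day, its error may be larger than simulated and the simulated counts too low. Overlaps between times are given beside the count for independent lists and the simulated count, and correlations across genes are given beside the simulated r, with covariances beside the simulated covariance. Genes are not independent replicates. Movement toward T84 was computed from 5 d minus 12 h, which shares no array with T84 minus untreated H4. Shares have Wilson 95% intervals, which treat genes as independent.

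Named genes were the 12 higher and 12 lower genes with the largest smallest difference over the 4 times, the 4 highest and 4 lowest at each time, the 6 with the smallest adjusted p in each direction, the 12 highest and 12 lowest in T84, up to 4 members per list for hydrocortisone and for T84, the 6 in each direction with the largest move toward T84, and a fixed set of glucocorticoid, inflammatory, enterocyte and lineage genes. Locus-number, open-reading-frame and antisense names were counted but not ranked. A gene from outside this rule is said to be chosen after its values were seen. Some items are not reported here.

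The fit was tested on simulated data with 200 changed genes. It recovered 7 of 88 tested genes shifted by 1 log2 unit and 46 of 83 shifted by 2, and called 0 of 16327 unshifted genes. Of 50 simulated lists of 25 genes with no shift, 5 fell outside the random range, and 50 of 50 did when shifted by 0.5.

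Alternatives were no floor, a floor of 6, a 3-fold threshold, the mean of a gene's probe sets, probe sets shared between transcripts left out, arrays centred on their median or on housekeeping genes, H4 arrays normalised again without T84, other limma options and filters, and each hydrocortisone array left out. The median used for centring was that of genes at or above the floor in all 6 arrays. Centring on the bacterial hybridisation controls and leaving out the 48 h and 5 d arrays together were chosen after the data were seen. The work used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.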

Results

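Expression of 19731 genes was measured in H4, a human fetal small intestinal epithelial cell line per the labels, and in T84, an adult human colonic epithelial line. H4 was profiled untreated and after 12 h, 24 h, 48 h and 5 d with 1 mM hydrocortisone, a glucocorticoid that acts through the nuclear receptor NR3C1. Each of the 6 groups held 1 array, so there were no replicates and differences at 1 time carry no error. The dose and its unit are as labelled and were not checked. The share of genes under the floor of 4 (log2) lay between 14.9% and 18.1% per array. The hybridisation controls, bacterial transcripts added in fixed amounts, were lower at 5 d than in untreated H4, with log2 differences of -0.58 for bioB, -0.62 for bioC, -0.55 for bioD and -0.35 for cre. At 48 h the same controls differed by -0.29, -0.38, -0.31 and -0.10. They differed by -0.33, -0.14, -0.08 and -0.10 at 12 h and by -0.28, -0.11, -0.07 and -0.17 at 24 h. The controls were thus lower than in untreated H4 in every hydrocortisone array. The signal at the 3' end of GAPDH minus that at its 5' end lay between -0.12 and -0.04 on the 6 arrays, and the same difference for ACTB lay between -0.22 and 0.24.

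What hydrocortisone did to H4 at every time was asked first. FKBP5 on chromosome 6, a co-chaperone that restrains the glucocorticoid receptor, rose 14.7-fold over the 4 hydrocortisone arrays (log2 3.88, SE 0.21, adjusted p 0.017 by limma, n = 4 against 1, higher in 4 of 4). Its difference was nearly flat in time, at 15.7-fold after 12 h and 15.6-fold after 5 d. TSC22D3, the anti-inflammatory leucine zipper protein GILZ, was 2.77-fold higher at 12 h and 6.94-fold higher at 5 d. LPL, the lipase that frees fatty acids from circulating lipoproteins, was 6.57-fold and 21.1-fold higher at these times. On the other side, CEMIP, which takes part in hyaluronan breakdown, was 15.3-fold lower at 12 h and 60.6-fold lower at 5 d, and the transcription factor SOX9 was 3.43-fold and 4.5-fold lower.

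A total of 22 genes were 2-fold or more higher at all 4 times and 41 were lower, where simulated arrays with no effect but a shared control gave 1.34 and 1.5. The higher set also held PCDH9, a protocadherin, THRB, a thyroid hormone receptor, the extracellular matrix gene THBS2, PXYLP1, RGS1, DGKI, OTULINL and DEFB1, which encodes an epithelial antimicrobial peptide and was at 4.30 (log2), near the floor, in untreated H4 and at 8.80 at 5 d. The lower set held NT5E, the ectonucleotidase CD73, the Wnt co-receptor LRP5, SOCS2, a suppressor of cytokine signalling, the GDNF co-receptor GFRA1, NIBAN1, ELMO1, RGS18, FIBIN and KRTAP1-5, each between 2.91-fold and 5.75-fold lower at every time, where ELMO1 (4.07 at 48 h), SOCS2 (4.05 at 48 h) and RGS18 (4.37 at 12 h) came near the floor. At 1 or more times a detected probe set of TSC22D3, THRB, PXYLP1, RGS1 or LRP5 did not go the same way, with 0 going 2-fold the other way. Part of this overlap may come from the shared untreated array. The simulated counts are a best case if that array came from another culture or day. They also come from arrays that each called few genes at 1 time, on average 10.43 higher and 10.55 lower. Without the 24 h array the higher set grew to 34 genes, and with 12 h and 24 h alone the lower set was 64. The mean of a gene's probe sets left 11 higher and 32 lower. The balance of directions turned when arrays were centred on the hybridisation controls, a test chosen after the data were seen, with 44 higher and 22 lower at all 4 times.

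Across the 16530 genes that limma tested in the pooled fit, FKBP5 was the 1 gene called higher and 0 were called lower, with 773 at an unadjusted p under 0.05. FKBP5 lost its call without the 12 h array (adjusted p 0.172), the 24 h array (0.0766) or the 5 d array (0.0619), and with the mean of its probe sets (0.0646), while its difference stayed large, with log2 of 3.85, 3.84, 3.85 and 3.61 in these 4 fits. With the 48 h and 5 d arrays both left out, the log2 difference of FKBP5 was 3.99 in a fit with 1 residual degree of freedom. Putting the 12 h or the 24 h array in place of the untreated one could not check this fit. Such fits pool the untreated array with a hydrocortisone array, so an effect of hydrocortisone widens their error.

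Genes that the glucocorticoid receptor is known to induce were higher as a group. The median of 33 measured targets was 0.61 (log2) at 12 h, 0.58 at 24 h, 0.31 at 48 h and 0.45 at 5 d, at percentiles of 100, 100, 99.99 and 100 of the random lists. Centred on the hybridisation controls the medians were 0.77, 0.74, 0.57 and 0.97. The lower median at 5 d than at 24 h therefore rests on the scaling, while that at 48 h stayed below that at 24 h. At 5 d, 12 targets were 2-fold or more higher and 3 were lower. In the pooled fit 14 of 32 passed when adjusted over the list alone, against 1 over all genes tested. They were FKBP5, TSC22D3, ALOX5AP, which supplies arachidonic acid to leukotriene synthesis, CRISPLD2, the kinase SGK1, ERRFI1, the phosphatase DUSP1, NFKBIA, which holds NF-kappaB in the cytoplasm, MAOA, SLC19A2, TMT1A, MT2A, MT1X and, in the lower direction, LPIN1. CDKN1C, a cell cycle inhibitor on this list, was lower, at 1.91-fold after 12 h and 6.57-fold after 5 d. The list of steroid receptors and steroid handling genes stayed within the random range, at percentiles of 20.9 to 63.5, and NR3C1 itself went from 10.77 (log2) to 10.13 at 5 d. FKBP5 was the 1 member of this list that passed, adjusted over the list alone or over all genes.

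Metallothioneins, small proteins that bind zinc and copper, were higher as a group. The median of 9 genes was between 0.68 and 0.81 (log2) at the 4 times, at percentile 100 at each time (0.84 to 1.31 when centred on hybridisation controls, the highest at 5 d), and 8 of 9 passed when adjusted over the list alone, against 0 over all genes. MT1E was 1.86-fold higher at 12 h and 1.87-fold at 5 d. These genes are nearly identical in sequence, so which members account for the signal is uncertain.

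**Figure D1:**
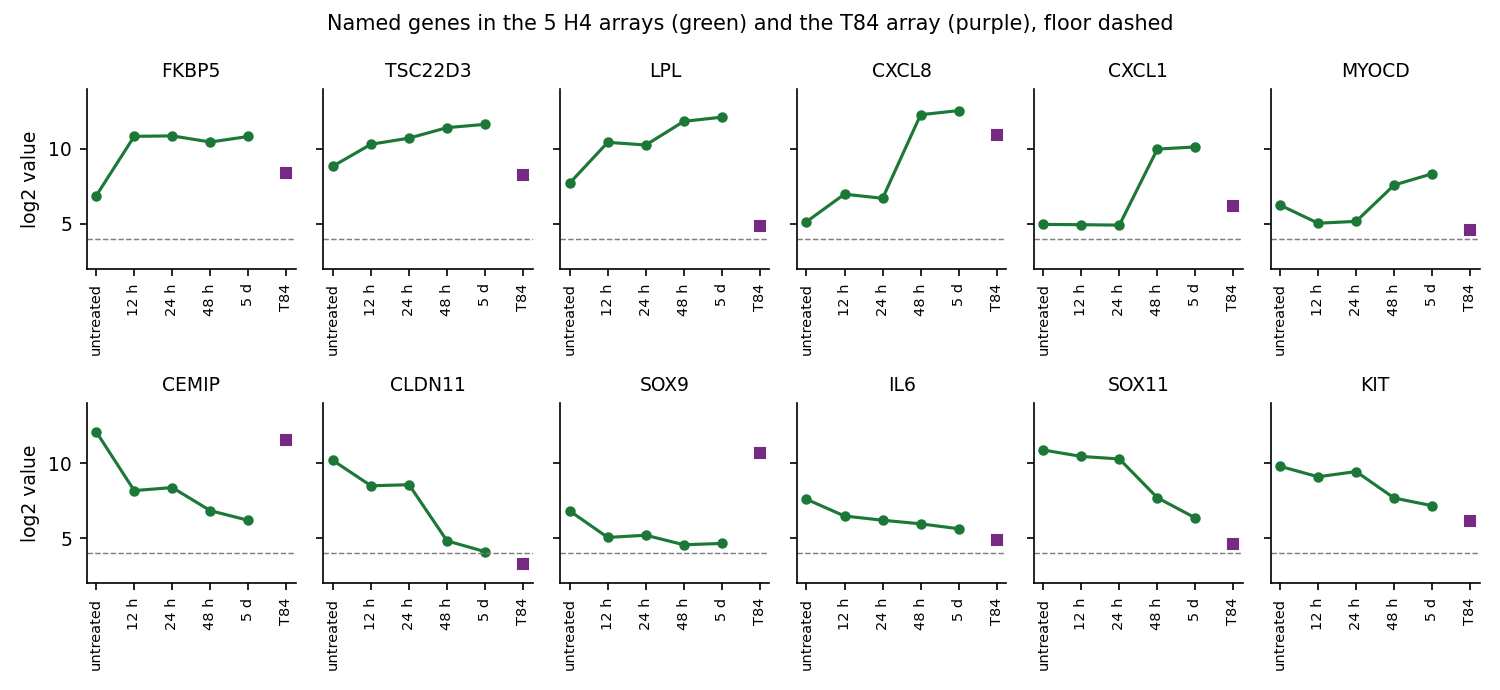
Deposited log2 values of 12 genes on the 6 arrays, with H4 in green, T84 in purple and the floor of 4 as a dashed line; KIT was chosen after its values were seen. FKBP5 is higher in each hydrocortisone array than in untreated H4, while CXCL8 and CXCL1 stand above 10 (log2) at 5 d.

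The early response was then compared with untreated H4 at 12 h and at 24 h. Besides the genes above, INSIG1, the sterol sensor that holds back cholesterol synthesis, was 2.42-fold lower at 12 h and 2.5-fold lower at 24 h, and FASN, the fatty acid synthase, was 3.27-fold lower at 24 h in 1 of its 2 probe sets. The median of 14 cholesterol synthesis genes was -0.36 at 12 h and -0.52 at 24 h (log2), at percentile 0 at both times (-0.20 and -0.36 when centred on hybridisation controls). At 48 h and 5 d it was 0.03 and 0.01, within the random range at percentiles of 67.7 and 76.3 (0.30 and 0.53 when centred on hybridisation controls). PTX3, a soluble pattern recognition protein, was 5.10-fold lower at 24 h. TLN1 was 4.71-fold lower in the 24 h array alone, in 1 of its 3 probe sets. The smooth muscle list had a median of 0.36 at 12 h (percentile 100) and 0.06 at 24 h (percentile 64.8).

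In number, 47 genes were higher and 98 lower at 12 h, and 46 and 126 at 24 h. With the mean of a gene's probe sets the counts were 27 and 63 at 12 h and 28 and 80 at 24 h. These arrays shared 26 higher and 64 lower genes, where independent sets would share 0.164 and 0.936 and simulated arrays with no effect 2.39 and 2.45. A simulated array called on average 10.43 genes higher and 10.55 lower, fewer than these arrays. Its overlap therefore cannot show how much of the sharing comes from the untreated array. The r of the differences across genes was 0.729 against a simulated 0.499, with a covariance of 0.0548 against 0.0209. The 12 h and 24 h arrays themselves differed 2-fold at 23 genes. The balance of directions rests on the scaling: centring on housekeeping genes gave 66 higher and 105 lower at 24 h (38.6% higher against 26.7%), and centring on the hybridisation controls gave 91 and 67 at 12 h (57.6% against 32.4%) and 98 and 81 at 24 h (54.7%).

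**Figure D2:**
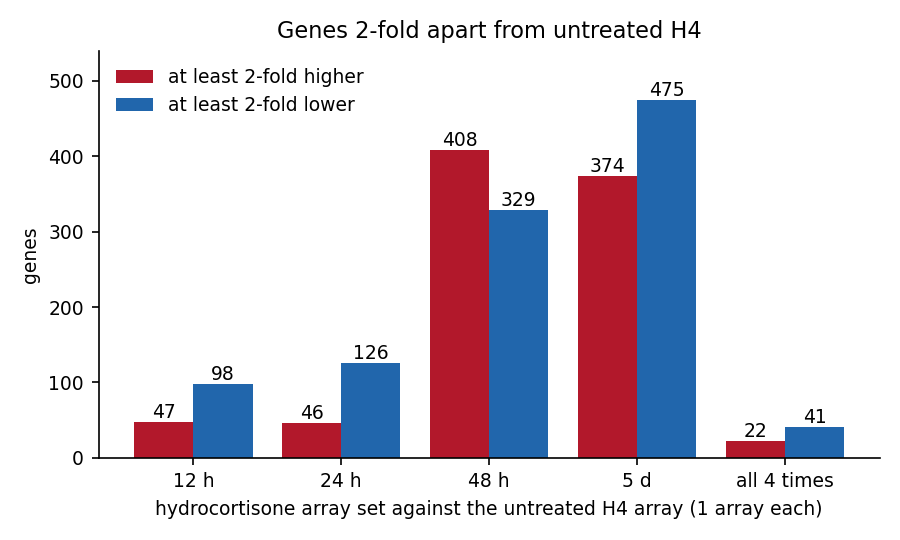
Number of genes 2-fold or more higher or lower than in untreated H4 at each time and at all 4 times. The bars reach 408 higher genes at 48 h and 475 lower genes at 5 d, against 47 and 98 at 12 h.

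At 48 h and 5 d a second set of genes stood apart from untreated H4. CXCL8, the neutrophil chemokine also called interleukin 8, was 3.59-fold higher at 12 h, 141-fold higher at 48 h and 171-fold higher at 5 d. CXCL1, a chemokine of the same class, differed by -0.02 (log2) at 12 h and was 36.2-fold higher at 5 d, CXCL6 was at least 8.18-fold higher at 48 h and, at 5 d, PF4V1, whose sequence is close to that of PF4, was at least 32.5-fold higher. INHBA, the activin A subunit, was 8.99-fold higher at 5 d, while the collagen gene COL14A1 and the melanosomal protein gene TYRP1 were at 4.55 and 4.57 (log2) in untreated H4 and at 8.66 and 9.11 at 5 d. CLDN11, a tight junction claudin, was at 10.18 (log2) in untreated H4, 8.49 at 12 h and 4.09, near the floor, at 5 d. SOX11, a transcription factor of embryonic tissues, the neuropeptide NPY and the growth factor MDK were 23.3-fold, 17.3-fold and 21.4-fold lower at 5 d.

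Genes of cell division and of the interferon response were lower in these late arrays. The median of 31 cell cycle genes was 0.04 at 12 h (percentile 77.4), 0.45 at 24 h (percentile 100), -0.71 at 48 h and -1.54 at 5 d (percentile 0 at both), and 22 of the 31 were 2-fold or more lower at 5 d. Among them the mitotic checkpoint kinase BUB1 went from 7.27 (log2) to 4.44, near the floor, and lower as well were CENPF 4.82-fold (in 2 of its 3 probe sets), CDC20 4.80-fold and the topoisomerase TOP2A 3.99-fold. The median of 25 interferon response genes was -0.81 at 48 h and -0.93 at 5 d (percentile 0 at both), after -0.04 at 12 h (percentile 19.4), and 10 of 25 were lower at each late time. IFIT1 was 12.2-fold lower at 5 d, IFIT2 8.76-fold and OAS1 3.32-fold, and TLR3, the receptor for double-stranded RNA, was 5.70-fold lower. The hybridisation controls were themselves lower in every hydrocortisone array, most at 5 d. Centring on them brought the cell cycle medians to -0.44 at 48 h and -1.02 at 5 d and the interferon medians to -0.54 and -0.40. In the pooled fit 0 members of either list passed, adjusted over the list alone or over all genes, in a fit that counts differences between times as noise.

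Matrix, contractile and TGF-beta responsive genes were higher late, and the mesenchymal and smooth muscle lists were also above the random range at 12 h. The mesenchymal and fibroblast list had medians of 0.69 at 48 h and 0.52 at 5 d (percentile 100 at both), with COL1A1 2.68-fold, COL5A1 2.83-fold and LUM 3.34-fold higher at 5 d. Its medians were 0.11 (percentile 97.9) and 0.00 (percentile 28.4) at 12 h and 24 h. ACTA2 and LOX passed when adjusted over this list alone, against 0 over all genes. The smooth muscle list had medians of 0.59 and 0.58 at 48 h and 5 d (percentiles 100 and 99.99), with CNN1 4.34-fold higher at 48 h. At 12 h and 24 h its medians were 0.36 (percentile 100) and 0.06 (percentile 64.8). ACTA2, which is on both lists, was the 1 member passing when adjusted over the smooth muscle list alone, against 0 over all genes. MYOCD, the master regulator of smooth muscle genes, was 2.31-fold lower at 12 h and 4.26-fold higher at 5 d. Medians of the TGF-beta and YAP list were 0.42 and 0.57 (percentile 100 at both) after percentiles of 40.8 and 39.1, with TGFB2 4.16-fold and CCN2 2.83-fold higher at 5 d and 0 members passing. Centred on the hybridisation controls, the 5 d medians of the mesenchymal, smooth muscle and TGF-beta lists were 1.05, 1.11 and 1.10, and that of the TGF-beta list at 48 h was 0.69. The unfolded protein list had a median of 0.37 at 48 h (percentile 99.97; 0.64 when centred on hybridisation controls, which took 5 d from 0.09 to 0.61), with PSAT1 3.72-fold and ASNS 2.26-fold higher, and lay within the random range at 12 h, 24 h and 5 d (percentiles 8.66, 18.7 and 95.2).

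**Figure D3:**
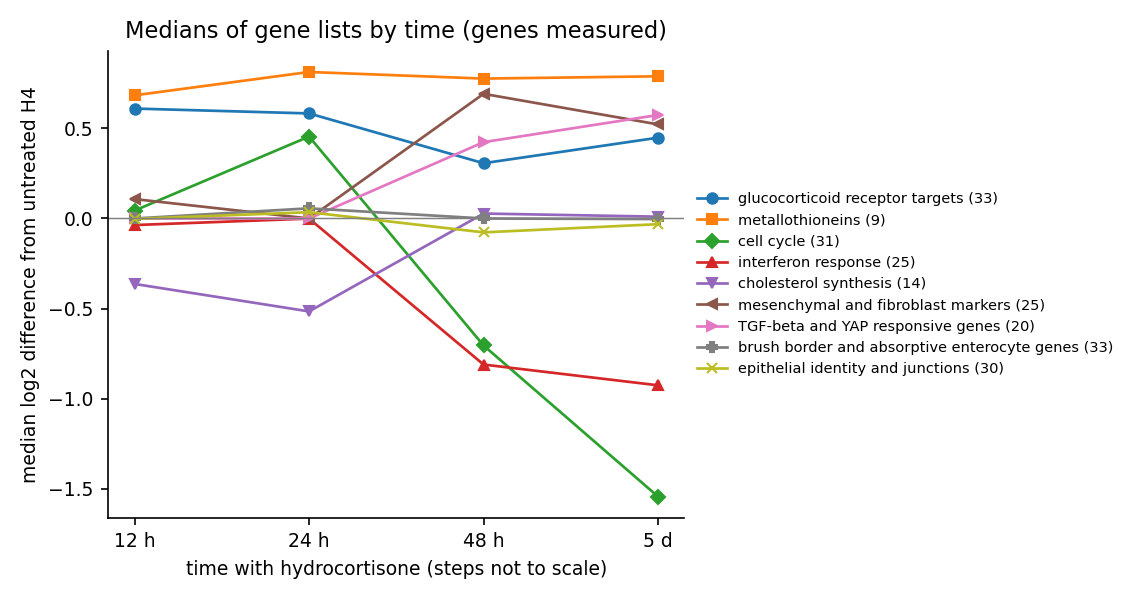
Median log2 difference from untreated H4 of 9 fixed gene lists at 12 h, 24 h, 48 h and 5 d, each line 1 list. The cell cycle line goes from 0.45 at 24 h to -1.54 at 5 d, while the glucocorticoid receptor target line stays between 0.31 and 0.61.

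In number, 408 genes were higher and 329 lower at 48 h, and 374 and 475 at 5 d. These arrays shared 295 higher and 269 lower genes against 11.6 and 11.9 for independent sets and a simulated 2.39 and 2.45. Each simulated array called on average only 10.43 genes higher and 10.55 lower. The simulated overlaps were thus small by construction and do not measure the part of the shared untreated array. The r of the differences across genes was 0.900 against 0.499, with a covariance of 0.188 against 0.0209, and part of this excess may come from the shared untreated array. Between early and late arrays r was lower, at 0.488 for 12 h with 48 h and 0.332 for 24 h with 5 d, while the covariances of 0.0569 and 0.0447 still exceeded the simulated one. The 24 h and 48 h arrays differed 2-fold at 718 genes, and the 48 h and 5 d arrays at 66. Centring on housekeeping genes, which lay -0.13 from untreated H4 in the 48 h array and -0.17 in the 5 d array, gave 531 higher and 250 lower at 48 h (68.0% higher against 55.4%) and 554 and 352 at 5 d (61.1% against 44.1%). Centring on the lower hybridisation controls gave 751 and 189 at 48 h (79.9%) and 1415 and 189 at 5 d (88.2%). The labels give the untreated array no time, so whether it matches any of the 4 times in culture is unknown and exposure was not separated from time.

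Inflammatory genes, which glucocorticoids are known to restrain, and Toll-like receptor genes were mixed. IL6 was 2.17-fold lower at 12 h and 3.91-fold lower at 5 d, and IL6 and the chemokine CXCL12 passed in the lower direction when adjusted over the list of inflammatory genes alone (0.0275 each), against 0 over all genes. The median of these 29 genes was 0.00 at each time, at percentiles of 31.5 to 63.9, but it is held there by members under the floor in both arrays. Over the 18 members detected at 48 h or in untreated H4 the median was -0.25, with 12 of 18 below 0. The 5 d array did not repeat this, with -0.01 over 19 detected members, 10 below 0 and 9 above. At 12 h and at 24 h the median over 18 detected members was 0.04. CD14, a co-receptor for bacterial lipopolysaccharide, was 2.91-fold lower at 12 h and 7.35-fold lower at 48 h, while TLR2 and TLR4 differed by at most 1.12-fold at every time. The Toll-like receptor and NF-kappaB list of 31 genes lay at percentiles of 24.1 to 74.8. In the pooled fit 0 members of this list, or of any list for which no count of passing genes is printed, passed when adjusted over the list alone.

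Genes of the mature enterocyte did not stand apart from random lists at any time, but many were too dim to tell. The 33 brush border and absorptive genes had percentiles of 11 to 84.6, with 0 members 2-fold higher at any time and 1 lower at 48 h and at 5 d, DPP4. Members under the floor in both arrays held the list median near 0. Over detected members it was 0.035 (log2) at 12 h (15 above 0, 10 below) and 0.12 at 24 h (19 above, 7 below). At 48 h it was -0.12 (7 above, 16 below) and at 5 d -0.05 (7 above, 17 below). The digestive enzyme genes LCT (lactase), SI (sucrase-isomaltase) and TREH (trehalase) were at 4.31, 2.95 and 3.55 (log2) at 5 d, and at 4.43, 2.93 and 3.68 in untreated H4. The 30 epithelial identity genes lay at percentiles of 23.5 to 52.5, with CLDN1 6.70-fold higher and KRT19 9.09-fold lower at 5 d, the latter in 1 of its 2 probe sets. The 21 secretory lineage genes lay at 24.8 to 59.5 and the 17 crypt and Wnt genes at 30.4 to 82.7, where SOX9 passed in the lower direction when adjusted over the list alone (0.00411) and 0 members passed over all genes. Lipid storage genes lay at 3.15 to 74.5, with LPL and ACSL1 higher and SCD lower when adjusted over the list alone and 0 over all genes. The hypoxia and glycolysis list was outside the random range at 24 h, with a median of -0.15 (percentile 0.43) that was 0.01 when arrays were centred on hybridisation controls, and within it at percentiles of 10.9 to 80.9 at other times. Markers of other cell types stayed in the random range, at 32.2 to 71.4 for 15 haematopoietic and endothelial genes and 17.8 to 55.6 for 16 neural genes, as did 12 housekeeping genes at 22.8 to 43.0.

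How far H4 stands from T84 was asked next. Many epithelial markers were far higher in T84 than in H4, although KRT19, CLDN11 and CLDN1 were well above the floor in untreated H4, at 9.74, 10.18 and 7.27 (log2). CDH1, which encodes E-cadherin, was at least 217-fold higher in T84 than in untreated H4, EPCAM at least 353-fold and the keratin KRT20 at least 257-fold. The intestinal lectin LGALS4, the intestinal cadherin CDH17 and the fatty acid binding protein FABP1 lay near the floor in untreated H4, at 4.12, 4.23 and 4.08 (log2), and at 12.66, 11.71 and 13.11 in T84. VIL1, the brush border protein villin, was 34.4-fold higher and the intestinal transcription factor CDX2 14-fold higher. In the other direction, the intermediate filament gene VIM was 277-fold lower in T84. The collagen genes COL6A3 and COL3A1, the growth factor receptor PDGFRA, the actin-binding CALD1 and the ion channel TRPA1 lay between 12.51 and 13.30 (log2) in untreated H4 and between 4.15 and 4.30, near the floor, in T84. NR3C1, the glucocorticoid receptor, was at 4.46 (log2) in T84 and 10.77 in untreated H4, and HSD11B2, which inactivates cortisol, was at least 12.4-fold higher in T84.

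Of the lists, epithelial identity had a median of 3.29 (percentile 100, with 25 of 30 members higher) and mesenchymal markers one of -6.05 (percentile 0, with 21 of 25 lower). Smooth muscle markers had -3.57 (percentile 0), metallothioneins -2.44 (0.02) and TGF-beta and YAP genes -0.96 (0.69). Cell cycle (0.96), hypoxia and glycolysis (1.12) and unfolded protein genes (1.12) were at percentile 100, cholesterol synthesis (0.72) at 99.98, secretory lineage (0.45) at 99.9, lipid storage (0.33) at 99.7, and crypt and Wnt genes (0.31) at 98.2, with LGR5 at 4.19 in untreated H4 and 8.25 in T84, and RNF43 24.9-fold higher. Interferon response genes had 0.38 (percentile 99.7), which was -0.01 when arrays were centred on housekeeping genes. The same centring took secretory lineage to 0.06, lipid storage and crypt and Wnt genes to 0.00, cholesterol synthesis to 0.34, cell cycle to 0.57, and hypoxia and unfolded protein genes to 0.73 each, while centring on the median took interferon response to 0.60, lipid storage to 0.55 and crypt and Wnt genes to 0.52. Within the random range were brush border genes as a whole (percentile 88.0, with 11 of 33 higher and 2 lower), glucocorticoid receptor targets (42.5), inflammatory genes (96.2), Toll-like receptor genes (89.8), steroid handling (94.6), neural (11.2), haematopoietic and endothelial (65.2) and housekeeping genes (95). Members under the floor in both arrays hold the brush border median, 0.08 (log2), and the inflammatory one, 0.12, near 0. Over the 26 brush border members detected in T84 or in untreated H4 the median was 0.72, with 17 above 0 and 8 below. Over the 21 detected inflammatory members it was 0.71, with 15 above 0 and 6 below. In number, 1885 genes were higher and 2710 lower in T84 than in untreated H4 (41.0% higher), and 1345 and 2023 against each of the 5 H4 arrays. In the limma fit of T84 against the 5 H4 arrays, 2741 of 16691 genes were called higher and 3465 lower, of which 1681 and 2445 by 2-fold or more. The T84 array sits -0.21 from untreated H4 in the median of genes at or above the floor in all 6 arrays, and 0.39 in its housekeeping genes. Centring on that median therefore gave 2437 and 2239 (52.1% higher) and centring on housekeeping genes 1250 and 3827 (24.6%).

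**Figure D4:**
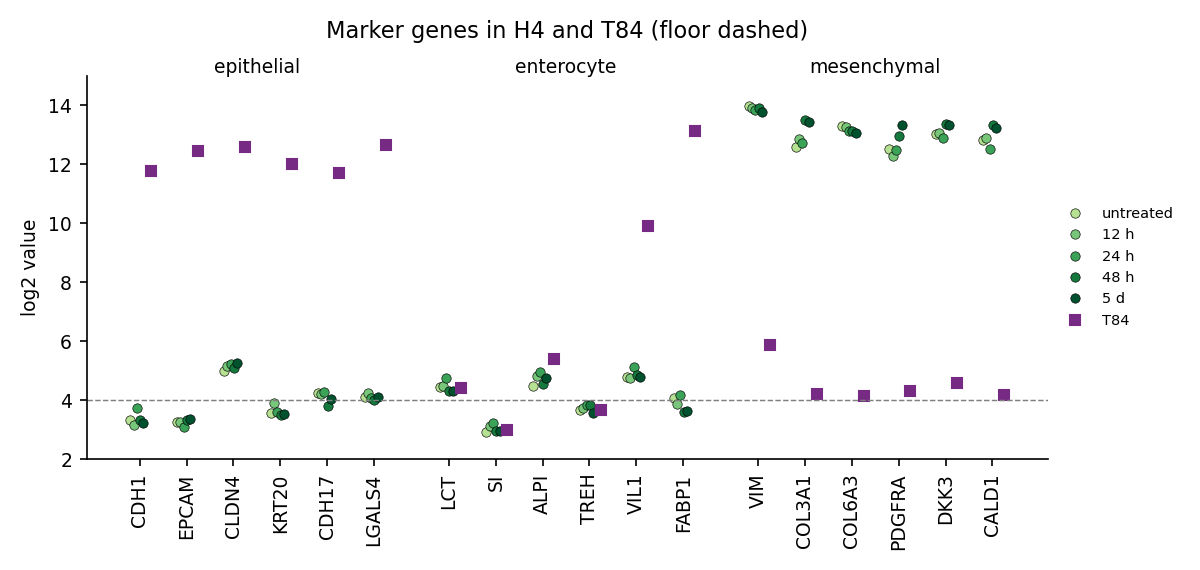
Deposited log2 values of epithelial, enterocyte and mesenchymal marker genes on the 5 H4 arrays and the T84 array, with the floor of 4 marked. CDH1 and EPCAM lie under the floor in untreated H4 and at 11.76 and 12.46 in T84, while VIM is at 13.99 in untreated H4 and 5.87 in T84.

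Whether hydrocortisone brought H4 nearer to T84, as the interest in differentiation stated in the title leads one to ask, was compared last. Some genes ended nearer to T84 at 5 d than at 12 h. AKR1C3, a steroid-metabolising reductase, was at 6.41 (log2) in untreated H4, 8.02 at 5 d and 9.39 in T84, and NCOA7 was at 7.42, 9.95 and 12.30. SOX11 was at 10.88, 6.34 and 4.61, and the scavenger receptor COLEC12 at 10.83, 6.32 and 4.38. Other genes went away from T84, such as INHBA, at 9.28, 12.45 and 3.32.

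Between 12 h and 5 d, 2184 of 4450 genes that separate T84 from untreated H4 moved toward T84, 49.1% (Wilson 95% interval 47.6 to 50.5), with 192 moving 2-fold toward it and 229 away. The share was 51.5% (50 to 53.0) between 12 h and 24 h, 47.0% between 12 h and 48 h and 47.4% between 24 h and 5 d, so the direction rests on the pair of times. Measured from the shared untreated array the shares were 59.6% at 12 h, 60.5% at 24 h, 53.4% at 48 h and 54.6% at 5 d, against a simulated 54.2% with no effect. The r with T84 across 17496 genes was 0.782 for untreated H4, 0.785 at 12 h and at 24 h, 0.773 at 48 h and 0.766 at 5 d, a difference of -0.0159 at 5 d. Of the genes higher at 5 d, 74 were higher in T84 and 145 lower, against 53.6 and 77.1 for independent sets and 3.14 and 1.24 in the simulated arrays. Of those lower at 5 d, 93 were higher in T84 and 224 lower, against 68.1 and 97.9, and 0.675 and 3.8. The simulated arrays called on average only 10.43 genes higher and 10.55 lower than their control, so their overlaps with T84 were small by construction. Part of the observed overlaps may come from the shared untreated array.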

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

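The tests of explanations in this part were chosen after the result was seen. Cell cycle genes went opposite ways at different times: their median was 0.45 (log2) at 24 h, -0.71 at 48 h and -1.54 at 5 d, and the difference between times was not tested. The next genes were chosen after their values were seen, because they stood 2-fold or more on opposite sides of untreated H4 at different times, and these differences were not tested either. Lower at 12 h and higher at 48 h were 3 genes, MYOCD, NCEH1 and OLR1. Lower at 24 h and higher at 48 h were 7, ALDH1L2, ATP11A, INMT, L1CAM, LRRC17, MYOCD and NCEH1. Lower at 24 h and higher at 5 d were 5, AKR1C3, ALDH1L2, INMT, LRRC17 and MYOCD. MYOCD, the regulator of smooth muscle genes, was the 1 gene lower at 12 h and higher at 5 d. TOX was the 1 gene higher at 12 h (1.05) and lower at 5 d (-1.08), and SPAG5, a mitotic spindle gene, the 1 higher at 24 h (1.02) and lower at 5 d (-1.26). Among the 13522 probe sets without a gene symbol of their own, which the comparisons did not use, 3 were 2-fold or more higher and 10 lower at all 4 times.

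Between the 24 h and 48 h arrays 718 genes differed 2-fold, against 23 between 12 h and 24 h and 66 between 48 h and 5 d. Noise of single probe sets is argued against in the 434 genes with another detected probe set, since 86.6% of those probe sets went the same way, and in the other 284, since 98.2% of them went the same way from 12 h to 5 d, in arrays not used to choose them. A shift of the whole 48 h array is argued against as the only cause, since the lowest count under 4 other scalings was 694. Weaker hybridisation that acts differently from probe to probe cannot be decided by these scalings. They move an array as a whole or keep the order of its values. Time in culture, or another culture or working day in place of exposure, cannot be told apart from hydrocortisone, because 0 untreated H4 arrays have a time point of their own. A late response to hydrocortisone may account for the step, and this remains a hypothesis.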

How the results depend on the processing

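Centring on hybridisation controls, leaving out the 48 h and 5 d arrays together and the limma fit for T84 were tests chosen after the data were seen. No paired analysis was possible because the labels give no replicate numbers and each group has 1 array. Of 153 recomputed values of the main comparisons, 113 stayed within 1.5 times the main count, or within the interval of a share, and 40 moved. The balance of directions turned under scaling: at 5 d 44.1% of called genes were higher, against 53.2% centred on the median, and for T84 41.0% against 52.1%. Of 3630 recomputed differences of named genes 2924 stayed close and 706 moved, and of 420 list medians 327 stayed and 93 moved. A 3-fold threshold, which is stricter by construction, left 11 higher and 19 lower genes at 12 h, 10 and 28 at 24 h, 129 and 114 at 48 h, 137 and 166 at 5 d, 1011 and 1660 for T84, and 5 and 10 at all 4 times. The mean of a gene's probe sets gave 27 and 63 at 12 h, 28 and 80 at 24 h, and 11 higher at all 4 times. Without the 24 h array 34 genes were higher at the remaining times, and without 48 h and 5 d 64 were lower, as fewer arrays had to pass. Centring on housekeeping genes gave 1250 genes higher in T84. The hybridisation controls were lower in every hydrocortisone array, most at 5 d. Centring on them gave 91 higher at 12 h, 98 and 81 at 24 h, and 751 and 189 at 48 h. At 5 d it gave 1415 and 189, and at all 4 times 44 and 22. The adjusted p of FKBP5 was 6.15e-06 to 0.172 over 12 alternatives, with log2 of the same direction in each, and was under 0.05 in 8. Limma called 0 genes higher with the mean of probe sets and without the 12 h, 24 h or 5 d array, with 722, 727, 960 and 586 at an unadjusted p under 0.05. Without both late arrays it called 101 higher and 168 lower, and 0 when the 12 h or the 24 h array was the lone one of those 3 (237 and 674 unadjusted). With any hydrocortisone array as the lone one of 5, 0 genes were called, with 228 to 833 unadjusted. The r with T84 at 5 d minus that of untreated H4 was -0.0271 with a floor of 6. The share moving toward T84, 49.1% with an interval that spans 50%, was 51.3% with a floor of 6, 47.5% with the mean of probe sets, 47.4% from 24 h to 5 d, 47.0% from 12 h to 48 h and 51.5% from 12 h to 24 h. Except where a construction is named, the cause was not tested. Signal over background limits folds of genes near the floor.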

Other observations

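The genes in this paragraph and the next, and all tests of explanations in this part, were chosen after the values were seen. No enrichment was tested for them. The 7 genes FOXF1, FOXF2, FOXL1, NKX2-3, TCF21, TBX2 and NR2F1, known as transcription factors of the gut mesoderm, lay between 8.52 and 11.95 (log2) in the 5 H4 arrays and between 3.78 and 5.48 in T84. In untreated H4 FOXF1 was at 11.95 and NKX2-3 at 11.40, against 3.81 and 3.78 in T84. The 8 genes ELF3, EHF, GRHL2, ESRP1, OVOL2, FOXA2, KLF5 and CDX1, known as regulators of epithelial cells, lay between 3.51 and 7.36 in the H4 arrays and between 7.14 and 11.11 in T84. KLF5 and CDX1 were well above the floor in untreated H4, at 7.36 and 6.89, and at 10.82 and 9.36 in T84. KIT, a receptor tyrosine kinase, was 1.62-fold lower at 12 h and 6.16-fold lower at 5 d.

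NR1D2, a repressor in the circadian loop, had log2 differences of -1.71 at 12 h, -0.19 at 24 h, -1.02 at 48 h and -0.92 at 5 d. BMAL1, which drives its transcription, had 0.92, 0.12, 1.23 and 0.73. CDKN2B, the cell cycle inhibitor p15, was 1.44-fold higher at 12 h and 16.0-fold higher at 5 d. DIO2, which activates thyroid hormone, was 2.54-fold and 18.5-fold higher at these times. WNT5A was 2.73-fold higher at 5 d, and WNT2 was 3.86-fold lower at 12 h, while the fixed crypt and Wnt list stayed within the random range.

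All 5 H4 arrays carried a mesenchymal profile, with collagens and VIM high and CDH1 and EPCAM under the floor. Epithelial probe sets that give no signal on this array type are excluded, since 25 of 30 epithelial list members were 2-fold or more higher in the T84 array. If H4 epithelial cells held these transcripts at T84 levels, a minority of fibroblasts would leave most of them within a small factor of T84. The lower quartile of T84 minus untreated H4 over the list was 1.96 (log2). T84 is an adult colonic line, so this test cannot decide if fetal epithelial cells hold lower levels. It also does not address a culture of mostly mesenchymal cells with few epithelial ones. Epithelial cells that changed toward a mesenchymal state in culture may explain the profile, and cannot be told apart from a mesenchymal origin of the line, which was not tested, with 0 arrays of an earlier passage or of the source tissue.

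CXCL8, CXCL1 and CXCL6 were higher in the 48 h and 5 d arrays although IL6 was lower. Signal of CXCL2 or CXCL3 transcripts is argued against, since these differed by at most 0.09 (log2) at 5 d although their probe sets gave signal in T84. Signal of PF4, PF4V1 or CXCL5 transcripts cannot be told apart. PF4V1 was higher by at least 5.02 and CXCL5 was under the floor on all 6 arrays. Leukocytes in the late cultures are argued against by an upper quartile of 0.22 over the haematopoietic and endothelial list, in which HBB, at 1.04, was the 1 gene 2-fold higher. No general rise of inflammatory genes was seen, though over few genes. Of the 16 other members of the inflammatory list at or above the floor at 5 d or in untreated H4, 0 were 2-fold higher at 5 d (26 were measured). Glucocorticoids are known to restrain inflammatory genes, so this cannot decide whether an inflammatory stimulus was present. Exposure to hydrocortisone and time in culture could each account for these chemokines, and the arrays do not separate them.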
